A study of Homo sapiens with 18 samples.

How the data were processed

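RNA sequencing data from 18 libraries of the THP-1 line were compared, made with 2 sgRNAs against SETDB1 (sgRNA 6 and sgRNA 9) or a non-targeting control guide (NTC), each at day 4 and day 7, with 3 libraries per group. Per the labels' protocols, guides were delivered by spin transduction, puromycin at 1 ug/ml was added from 48 hours, and libraries were made from 0.5 ug of total RNA with the TruSeq RNA kit version 2, which does not mark strand. Reads from a gene and from an overlapping or antisense gene therefore cannot be told apart. Nothing in the labels says that the 3 libraries of a group come from separate cultures. If they do not, the p-values measure only the spread between these samples.

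The deposited gene table holds raw counts of reads per gene, as whole numbers with no normalization. The submitters' processing notes name CASAVA 1.8, GSNAP, Bowtie and edgeR and the builds GRCh38 and hg19 without giving each a role, and the counting tool and annotation are not given in the sources used here. The deposited repeat table holds estimated counts per repeat subfamily, which its title calls RepEnrich fraction counts. RepEnrich shares a read that maps to several subfamilies among them, and the values in the file are whole numbers. In the authors' 4 deposited tables of changed genes, per the file headers, one column holds a log2 fold change and another an FDR, an adjusted p-value, and only genes with a small FDR are listed. Library columns were matched to samples by the identifiers in the labels, and 0 columns belonged to another series.

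The gene table has 18619 genes. Of their symbols, 27 had been turned into dates by a spreadsheet. Of these, 20 were tested, and none was named. Symbols were placed on GRCh38 with GENCODE release 44 through current and older names, which gave positions for 18497. That annotation may differ from the one the authors counted on. Low counts were filtered with filterByExpr by group, which kept 13004 genes. Counts were scaled by TMM and tested in edgeR 4.0.16 (R 4.3.3) with glmQLFit and glmQLFTest, in a single fit of all 18 libraries with 1 mean per group, 12 residual degrees of freedom and no block. The biological coefficient of variation was 5.43% and the prior degrees of freedom were 16.5. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that comparison. The comparisons were each guide against NTC at each day, the mean of both guides against NTC, the guides against each other, NTC between days, and the difference of each guide's change between days. Levels are given as TMM-scaled CPM (counts per M, mega), as mean and SD over 3 libraries, and log2 fold changes carry their standard error (SE).

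Estimated counts of repeats, rounded to whole numbers (which the file already holds), were tested the same way, with the TMM-scaled gene total of each library as its size, since the repeat table holds part of a library. Subfamilies with 10 or more counts in at least 2 libraries were kept, which left 1012 of 1116. The sgRNA 9 day 7 replicate 2 library, which the labels exclude from the repeat comparison, was left out of it. Totals per repeat family (43 with enough counts) were compared with limma 3.58.1 on log2 of counts per M gene counts plus 0.5, and with 2-sided exact permutation tests, whose smallest possible p was 0.1 for 3 libraries against 3 and for 2 against 3. Fisher's exact tests of repeat classes among the called subfamilies were added after the files were seen.

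Gene lists written before the files were seen were tested with camera in limma on voom values, with the preset correlation between genes of 0.01, adjusted over all 80 pairs of list and guide comparison. The 20 lists were interferon-stimulated genes, nucleic acid sensing, interferon ligands, MHC class I antigen presentation, inflammatory cytokines and NF-kB targets, apoptosis, p53 targets, cell cycle, monocyte and macrophage maturation, leukaemic progenitor programme, heterochromatin machinery, germline genes, ZNF genes, clustered protocadherins, integrated stress response and UPR, ribosomal proteins, mitochondrially encoded mRNAs, and lymphoid, erythroid and megakaryocytic, and epithelial and fibroblast markers. Members past the test were also counted after adjustment over the list alone. List tests of the day differences, of the NTC cells between days and of the guides against each other were added later and adjusted over those comparisons.

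Genes named in the text followed a rule fixed beforehand. It took SETDB1, the 6 largest rises and 6 largest falls by log2 fold change per guide comparison among called genes with an average log2 CPM of 1 or more and no overlap between the libraries of both groups, and up to 4 members per list and comparison with the smallest adjusted p. The 3 largest changes in each direction were taken for the other comparisons. For repeats, the rule took the 6 largest rises and 4 largest falls per comparison. Genes with near-identical copies (chemokine, histone, HLA, protocadherin, ZNF and ribosomal protein genes, the last with many processed pseudogenes) are uncertain where reads could be split between copies, since the counting is not described.

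The test was run on simulated data, with counts drawn from the means, dispersions and library sizes of these libraries and 200 seeded changes, in 5 simulations each. For sgRNA 6 at day 4, 44.7% of genes changed 1.25-fold, 79.7% of those changed 1.5-fold and 93.6% of those changed 2-fold were recovered, and 60 of 784 calls (7.65%) were false. For sgRNA 9 at day 7 the shares were 42.4%, 78.2% and 94.2%, with 32 false of 745 calls (4.30%). For repeats with sgRNA 6 at day 7 they were 30.6%, 71.8% and 95.2%, with 30 false of 685 calls (4.38%). For sgRNA 6 at day 4, camera called the seeded list. The simulated genes vary independently of each other, so the simulation does not measure false calls of lists whose genes vary together. The seeded genes were few beside those called in the real comparisons, and they rose and fell equally often. The shares of false gene calls therefore do not cover errors of TMM scaling when many genes change. Intervals for genes with 3 or fewer counts in a group are exact Clopper-Pearson 95% intervals and cover counting error only.

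Alternatives tried were RLE size factors, library totals without TMM, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, only the groups compared, a log2 fold change of 1 or more, each library left out in turn, other library sizes for repeats, an estimated correlation between genes in camera, and other pseudocounts for family totals. Library totals without TMM, and a fit without the 2 day 4 libraries rich in repeat reads, were added after the files were seen.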

Results

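Gene and repeat expression was measured by RNA sequencing in THP-1, a human acute monocytic leukaemia line, after Cas9 guides against SETDB1, a histone methyltransferase that represses retroelements and some genes. The comparisons ask which genes and repeats differ from cells with a non-targeting control (NTC) guide at day 4 and day 7, and whether both guides give the same changes. Each of the 6 groups (sgRNA 6, sgRNA 9 and NTC at each day) had 3 libraries. Gene counts per library lay between 10.58 M and 13.96 M (M, mega). Group means ± SD were 13.1 ± 0.788 M for sgRNA 6, 13.4 ± 0.334 M for sgRNA 9 and 13.0 ± 0.253 M for NTC at day 4, and 12.5 ± 0.910, 12.3 ± 0.719 and 11.4 ± 0.692 M at day 7. Between 14632 and 15215 genes had at least 1 count in a library. On the first principal component of tested genes (70.0% of the variance) the guide libraries of day 7 lay apart from all NTC libraries, with the guide libraries of day 4 between them, and the component after it (12.3%) held apart the NTC libraries of both days. Counts in the repeat table lay between 1.42 M and 2.01 M per library, apart from sgRNA 9 day 7 replicate 2 with 0.645 M, of which 81.2% were ribosomal RNA. In the day 4 guide groups, sgRNA 6 replicate 1 and sgRNA 9 replicate 3 held 25.2% and 23.9% more transposable element reads per M gene counts than the mean of the other 2 libraries of their group.

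SETDB1 transcript (GRCh38, chromosome 1, 150926263 to 150964744, plus strand) was lower with both guides at both days. At day 4 it averaged 137 ± 8.79 CPM with sgRNA 6 and 135 ± 11.1 CPM with sgRNA 9, against 241 ± 21.0 CPM in NTC (SD, n = 3 each), which is 57.0% and 56.3% of the NTC level. At day 7 it averaged 144 ± 10.0 and 154 ± 4.34 CPM, against 228 ± 3.69 CPM, or 63.2% and 67.2%. The log2 fold changes were -0.81 ± 0.07, -0.83 ± 0.07, -0.66 ± 0.07 and -0.57 ± 0.07 (SE), with edgeR adjusted p of 6.43e-11, 3.64e-11, 3.19e-10 and 6.24e-09. The size of the fall depended on the scaling. Library totals in place of TMM gave -0.65 ± 0.07, -0.67 ± 0.07, -0.29 ± 0.07 and -0.21 ± 0.07, with a largest adjusted p of 0.00517. The median of all genes then lay at 0.16, 0.17, 0.42 and 0.42, against 0.003, 0.004, 0.05 and 0.06 with TMM. In TMM-scaled CPM, in each comparison, all 3 guide libraries lay below all 3 NTC libraries, and the 2-sided exact permutation p was 0.1, the smallest that 3 against 3 allows. A guide can disrupt the protein without lowering the transcript, so these levels check the labels and do not measure the knockout.

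**Figure D1:**
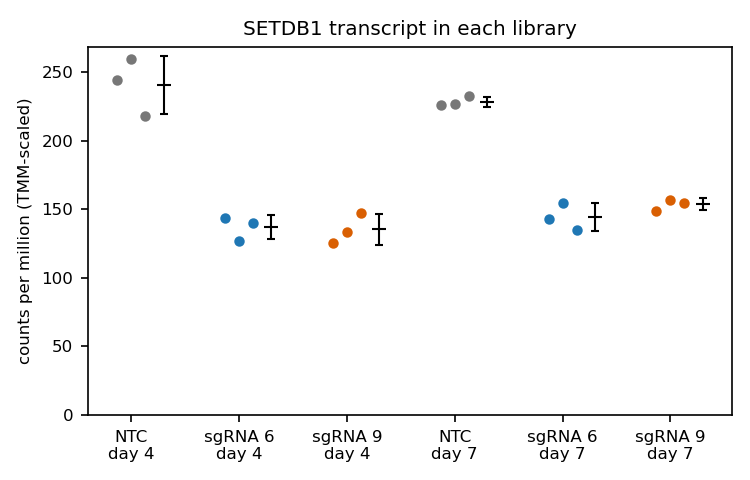
SETDB1 level in each library, as TMM-scaled counts per M, by group and day. Points are libraries (n = 3 per group) and bars show the mean with SD. The guide libraries lie below every NTC library of the same day, with group means of 137, 135, 144 and 154 CPM against 241 and 228 CPM.

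With sgRNA 6 at day 4, the largest rises included the interferon-induced genes IFIT2 and IFIT3, which limit viral RNA translation, and ERV3-1, the envelope gene of an endogenous retrovirus. IFIT2 averaged 191 ± 20.4 CPM against 40.5 ± 5.42 CPM in NTC (log2 fold change 2.23 ± 0.08, adjusted p = 4.23e-18), and IFIT3 averaged 430 ± 15.9 against 106 ± 6.44 CPM (2.02 ± 0.07, adjusted p = 2.08e-19; n = 3 each). ERV3-1 (chromosome 7, 64990356 to 65006743, minus strand) rose from 15.5 ± 4.26 to 62.9 ± 16.3 CPM, a log2 fold change of 2.01 ± 0.19. The double-stranded RNA sensor TLR3 (2.05 ± 0.32), the axonemal dynein DNAH3 (2.59 ± 0.39) and the carbonic anhydrase CA3 (2.02 ± 0.24) also rose, all from under 2 CPM in NTC. Among the falls were the glycolytic enzyme ALDOC (-1.95 ± 0.25), the creatine transporter SLC6A8 (-1.81 ± 0.23), TMEM45A (-1.62 ± 0.21), C12orf75 (-1.78 ± 0.17), C1QL1 (-1.58 ± 0.19) and TBC1D30 (-2.82 ± 0.31). TBC1D30 and SLC6A8 varied widely between NTC libraries, at 57.9 ± 25.1 and 114 ± 41.6 CPM. Of 13004 genes tested, 6108 were called, 2853 higher and 3255 lower, and 320 of them changed 2-fold or more (248 higher, 72 lower). With library totals in place of TMM, 4878 were higher and 1853 lower, and the median of all genes lay 0.16 higher on the log2 scale.

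With sgRNA 9 at day 4, ERV3-1 (1.99 ± 0.19), DNAH3 (2.84 ± 0.37), CA3 (2.06 ± 0.24) and IFIT2 (1.98 ± 0.08) were again among the largest rises. CA2, which encodes an abundant carbonic anhydrase, averaged 5899 ± 131 CPM against 1597 ± 51.3 CPM in NTC (log2 fold change 1.89 ± 0.06, adjusted p = 9.48e-19, n = 3 each). The secreted macrophage protein CD5L rose by 1.96 ± 0.37 on the log2 scale. The largest falls were the neuropeptide gene GAL (-1.43 ± 0.10), C1QL1 (-1.29 ± 0.18), the nucleotide hydrolase DNPH1 (-1.29 ± 0.07), UGT3A2 (-1.26 ± 0.09), C12orf75 (-1.25 ± 0.16) and the microtubule regulator STMN1 (-1.20 ± 0.08, from 1312 ± 76.8 to 573 ± 24.7 CPM). In all, 6718 genes were called, 3259 higher and 3459 lower, and 335 changed 2-fold or more (283 higher, 52 lower). With library totals in place of TMM the split was 5085 higher and 2056 lower, with the median of all genes at 0.17 (0.004 with TMM).

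Most interferon-stimulated genes rose at day 4. Of 45 tested, 40 rose and none fell with sgRNA 6 (41 and 0 adjusted over the list alone), with a median log2 fold change of 1.07, and 40 rose and 3 fell with sgRNA 9 (40 and 3 adjusted over the list alone), with a median of 0.86. IFIT1 rose by 1.64 ± 0.06 with sgRNA 6 and 1.31 ± 0.06 with sgRNA 9, OASL by 1.32 ± 0.06 with sgRNA 6 and SAMD9 by 1.51 ± 0.08 with sgRNA 9. Camera gave adjusted p = 1.34e-39 and 1.35e-26 at the preset correlation, and 0.0300 and 0.0491 with an estimated correlation. Genes of nucleic acid sensing rose with them. Of 19 tested, 13 rose and 2 fell with sgRNA 6 (13 and 2 adjusted over the list alone), among them the cytosolic RNA sensors DDX58 (1.40 ± 0.06) and IFIH1 (1.13 ± 0.06) and the DNA sensor IFI16 (0.99 ± 0.06). With sgRNA 9, 11 rose and 1 fell (12 and 1 adjusted over the list alone), with DDX58 at 1.16 ± 0.06. Their camera adjusted p was 7.79e-06 with sgRNA 6 (adjusted p = 0.0491 with an estimated correlation) and 0.000169 with sgRNA 9 (adjusted p = 0.103 with an estimated correlation). Only 2 interferon ligand genes passed the filter. Of these, IFNB1 rose by 2.28 ± 0.39 and 1.91 ± 0.41, from 0.3 CPM to 1.7 and 1.3 CPM, and the pair was not called as a list (adjusted p = 0.241 and 0.495; 1 rose and 0 fell with each guide, also adjusted over the list alone).

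Ribosomal protein genes moved the other way at day 4. Of 77 tested, 62 fell and none rose with sgRNA 6 (63 and 0 adjusted over the list alone; median -0.47), and 67 fell and none rose with sgRNA 9 (69 and 0 adjusted over the list alone; median -0.54). Library totals in place of TMM gave medians of -0.31 and -0.37, or -0.47 and -0.54 relative to all genes. RPS20 fell from 1751 CPM to 1061 and 1027 CPM, log2 fold changes of -0.72 ± 0.06 and -0.77 ± 0.06. Camera gave adjusted p = 3.09e-20 and 2.19e-23 (adjusted p = 0.246 and 0.215 with an estimated correlation). ZNF genes, which encode zinc finger proteins, many of them KRAB-type repressors, rose. Of 436 tested, 230 rose and 18 fell with sgRNA 6 (238 and 20 adjusted over the list alone; median 0.34), and 237 rose and 22 fell with sgRNA 9 (240 and 22 adjusted over the list alone; median 0.36). Examples are ZNF469 (0.94 ± 0.09 and 0.89 ± 0.09) and, in the other direction, ZNF511 (-0.57 ± 0.06 and -0.61 ± 0.06). Their camera adjusted p was 4.44e-11 and 1.76e-10 (adjusted p = 0.188 for both guides with an estimated correlation). Clustered protocadherins, adhesion genes that lie in tandem arrays, had 22 of 46 higher with sgRNA 6 and 23 with sgRNA 9, and none lower (the same numbers adjusted over the list alone), with medians of 0.33 and 0.40. PCDHB14 rose by 0.90 ± 0.15 and 1.06 ± 0.14. By camera the adjusted p was 0.000169 and 0.00724 (adjusted p = 0.506 and 0.720 with an estimated correlation).

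Smaller changes at day 4 touched 4 further lists. Apoptosis genes had 13 of 23 higher and 4 lower with sgRNA 6 (13 and 4 adjusted over the list alone; median 0.25; adjusted p = 0.0363, and 0.246 with an estimated correlation), with TNFSF10, the death ligand TRAIL, up by 1.35 ± 0.10 and BAX down by -0.61 ± 0.06. Library totals gave a median of 0.41, or 0.24 relative to all genes. That call was lost without NTC day 4 replicate 2 (adjusted p = 0.0699), under library totals (0.0992) and without the 2 libraries rich in transposable element reads (0.0578), and the list was not called with sgRNA 9 (11 higher, 4 lower; 13 and 4 adjusted over the list alone; adjusted p = 0.0816). Targets of p53 had 12 of 19 higher and 2 lower with sgRNA 9 (12 and 2 adjusted over the list alone; median 0.35; adjusted p = 0.0238, and 0.215 with an estimated correlation), among them MDM2 (0.50 ± 0.08) and TNFRSF10B (0.79 ± 0.12). Without NTC day 4 replicate 3 that adjusted p was 0.0522, and with sgRNA 6 the list was not called (10 higher, 3 lower; 10 and 4 adjusted over the list alone; adjusted p = 0.192). Cell cycle genes had 12 of 27 lower and 1 higher with sgRNA 6 (12 and 1 adjusted over the list alone; adjusted p = 0.00976, and 0.763 with an estimated correlation), with the thymidylate synthase TYMS at -0.56 ± 0.05. Their median of -0.12 turned to 0.04 with library totals in place of TMM, where the call was lost (adjusted p = 0.360), as it was without the 2 libraries rich in transposable element reads (0.0578). With sgRNA 9 they were not called (10 lower, 2 higher, also adjusted over the list alone; adjusted p = 0.133), and the median of -0.08 likewise turned to 0.08. Mitochondrially encoded mRNAs had 10 of 13 higher with sgRNA 9 (10 adjusted over the list alone; median 0.38; adjusted p = 0.00651, and 0.763 with an estimated correlation), with MT-CO1 at 0.67 ± 0.13. With sgRNA 6, 1 was higher (0 adjusted over the list alone; adjusted p = 0.578, 0.0481 without sgRNA 6 replicate 1, and 0.0382 without both libraries rich in transposable element reads).

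Several groups were mixed at day 4 and not called with either guide. In MHC class I antigen presentation, TAP1 rose (0.66 ± 0.05 and 0.41 ± 0.05) while HLA-C fell, with 7 higher and 4 lower of 13 with sgRNA 6 and 6 higher and 4 lower with sgRNA 9. Inflammatory cytokines and NF-kB targets had 4 of 15 higher and 1 lower, then 6 and 1, with CCL5 down by -0.75 ± 0.08 and -0.89 ± 0.08. Monocyte and macrophage genes had 3 of 19 higher and 5 lower, then 9 and 5, with LYZ at -0.44 ± 0.07 with both guides. In the leukaemic progenitor programme 4 of 15 rose and 3 fell with each guide, with HOXA9 up (0.43 ± 0.06 and 0.36 ± 0.06) and MYC down (-0.31 ± 0.05 and -0.37 ± 0.05). The heterochromatin machinery had 4 of 17 higher and 4 lower with each guide, with the SETDB1 partner ATF7IP up (0.67 ± 0.08 and 0.81 ± 0.08) and CBX5, the gene of HP1 alpha, down (-0.50 ± 0.06 and -0.58 ± 0.06). Integrated stress response and UPR genes had 2 of 15 higher and 6 lower, then 4 and 6, with XBP1 at -0.55 ± 0.05 and -0.50 ± 0.05. Germline genes had 1 of 9 higher and 2 lower, then 1 and 1. Markers of other cell types gave 1 of 7 lymphoid genes higher and 1 lower, then 1 and 2, 1 of 2 erythroid and megakaryocytic genes lower, then none, and 1 of 3 epithelial and fibroblast genes higher and 1 lower with each guide. Adjusted over the list alone, the counts that differed were 3 and 1 for inflammatory, 4 and 5 for heterochromatin and 3 and 6 for stress response genes with sgRNA 6, and 1 and 2 for epithelial and fibroblast genes with sgRNA 9. Median, mean and camera direction differed in sign for the leukaemic progenitor and heterochromatin lists with both guides, for lymphoid markers with sgRNA 6 and for germline genes with sgRNA 9.

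With sgRNA 6 at day 7, the largest rises were the formyl peptide receptor FPR3, the tryptophan dioxygenase TDO2 and DNAH3. TDO2 (chromosome 4, 155854738 to 155920406, plus strand) averaged 298 ± 15.8 CPM against 9.14 ± 0.753 CPM in NTC (log2 fold change 5.03 ± 0.13, adjusted p = 1.41e-22, n = 3 each). FPR3 had 262 counts against 3 over the NTC libraries of that day, a ratio of 61.5 (95% counting interval 20.8 to 300.2). DNAH3 (4.83 ± 0.27), the transcription factor ZNF366 (3.99 ± 0.23), the tight junction gene OCLN (3.98 ± 0.31) and ERV3-1 (3.87 ± 0.19, 207 ± 32.0 against 14.2 ± 0.853 CPM) followed. The largest falls included the cytokine TNF (-2.98 ± 0.17, 2.64 ± 0.603 against 21.1 ± 5.08 CPM), GAL (-3.07 ± 0.12), PNCK (-2.93 ± 0.21), TBC1D30 (-3.59 ± 0.45), and CCL4L2 (-3.66 ± 0.32) and the histone gene HIST1H2BH (-3.08 ± 0.20), both of which have near-identical copies. For CCL4L2 the NTC level at day 7 was itself higher than at day 4. Of the genes tested, 10064 were called, 5219 higher and 4845 lower, and 3733 changed 2-fold or more (2174 higher, 1559 lower). With library totals in place of TMM the split was 7347 higher and 3086 lower, and the median of all genes lay at 0.42 (0.05 with TMM).

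With sgRNA 9 at day 7, the same 6 genes led the rises, with TDO2 at 4.86 ± 0.13 (266 ± 32.8 CPM), DNAH3 at 4.90 ± 0.27, ZNF366 at 3.86 ± 0.24, OCLN at 3.84 ± 0.32 and ERV3-1 at 3.79 ± 0.19. FPR3 had 223 counts against 3, a ratio of 53.6 (95% counting interval 18.1 to 262). The falls were led by TBC1D30 (-3.36 ± 0.44), CCL4L2 (-3.30 ± 0.31, against the same raised NTC level), the kinase gene PNCK (-2.96 ± 0.21), GAL (-2.91 ± 0.11), HIST1H2BH (-2.81 ± 0.20) and ALDOC (-2.81 ± 0.28). Calls numbered 9951, with 5228 higher and 4723 lower, and 3404 genes changed 2-fold or more (1969 higher, 1435 lower). With library totals in place of TMM the split was 7378 higher and 2986 lower, with the median of all genes at 0.42 (0.06 with TMM).

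Ribosomal protein genes were lower at day 7. Of 77 tested, 76 fell with sgRNA 6 and 75 with sgRNA 9, and none rose (the same numbers adjusted over the list alone), with medians of -1.58 and -1.49, and 69 and 67 fell 2-fold or more. RPS24 fell from 2218 CPM to 498 and 516 CPM (-2.16 ± 0.07 and -2.10 ± 0.07) and RPL13 by -1.83 ± 0.06 and -1.71 ± 0.06. Their share of gene counts was 2.07 ± 0.0299% and 2.18 ± 0.156% (SD, n = 3), against 5.18 ± 0.219% in NTC. Camera gave adjusted p = 3.41e-25 with each guide (adjusted p = 0.215 with an estimated correlation). With library totals in place of TMM the medians were -1.21 and -1.13, or -1.62 and -1.55 relative to all genes. Cell cycle genes fell with them, 25 of 27 with sgRNA 6 and 26 with sgRNA 9, with 1 higher in each (the same numbers adjusted over the list alone), and medians of -0.79 and -0.92. Library totals gave -0.42 and -0.56, or -0.83 and -0.98 relative to all genes. TYMS (-1.45 ± 0.05 and -1.46 ± 0.05) and the mitotic cyclin CCNB2 (-1.67 ± 0.08 and -1.68 ± 0.08) were among them. Their camera adjusted p was 1.28e-08 and 2.76e-10 (adjusted p = 0.303 and 0.246 with an estimated correlation). Mitochondrially encoded mRNAs were lower too, 13 of 13 with sgRNA 6 and 12 with sgRNA 9 (the same numbers adjusted over the list alone), with medians of -0.63 and -0.42 and MT-CO3 at -0.96 ± 0.07 and -0.77 ± 0.07. At the preset correlation camera gave 0.00443 and 0.0248 as adjusted p (adjusted p = 0.720 and 0.846 with an estimated correlation). Under library totals their medians were -0.26 and -0.07 (-0.68 and -0.48 relative to all genes), with 3 of the 13 above 0 with sgRNA 9, whose call was lost (adjusted p = 0.0866). That call was also lost without NTC day 7 replicate 2 (adjusted p = 0.0635).

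ZNF genes and protocadherins were higher at day 7. Of 436 ZNF genes, 300 rose and 33 fell with sgRNA 6 (300 and 33 adjusted over the list alone), and 306 rose and 33 fell with sgRNA 9 (306 and 34 adjusted over the list alone), with medians of 0.65 and 0.64. ZNF629 rose from 8.6 CPM to 53.8 and 51.7 CPM (2.65 ± 0.11 and 2.59 ± 0.11). Camera gave adjusted p = 5.51e-08 and 9.26e-09 (adjusted p = 0.215 with an estimated correlation, both guides). Library totals gave medians of 1.02 and 1.00, or 0.61 and 0.58 relative to all genes. Of 46 protocadherins, 41 and 40 rose and none fell (the same numbers adjusted over the list alone), with medians of 0.87 and 0.93. PCDHGA8 rose by 1.52 ± 0.08 and 1.43 ± 0.08. Their camera adjusted p was 4.01e-07 and 7.47e-08 (adjusted p = 0.303 and 0.291 with an estimated correlation).

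Interferon-stimulated genes were split at day 7. Of 45, 27 rose and 8 fell with sgRNA 6 and 27 rose and 6 fell with sgRNA 9 (the same numbers adjusted over the list alone), with medians of 0.39 and 0.38. Library totals gave 0.75 and 0.74, or 0.34 and 0.32 relative to all genes. IFIT2 (2.24 ± 0.08 and 2.22 ± 0.08) and the antiviral radical enzyme RSAD2 (1.89 ± 0.07 and 1.90 ± 0.07) rose, while IFI6, a mitochondrial antiviral protein, fell from 3095 CPM to 1135 and 1199 CPM (-1.45 ± 0.05 and -1.37 ± 0.05). Camera gave adjusted p = 0.00976 and 0.00229 (adjusted p = 0.720 and 0.696 with an estimated correlation). Nucleic acid sensing genes were not called (adjusted p = 0.0570 with each guide), with 13 of 19 higher and 3 lower with sgRNA 6, and 13 and 4 with sgRNA 9 (the same numbers adjusted over the list alone). They were called without NTC day 7 replicate 2 (adjusted p = 0.0455 with each guide) and, with sgRNA 9, without its replicate 1 (0.0437). The RNA editor ADAR rose by 1.89 ± 0.10 and 1.70 ± 0.09, and TMEM173, which encodes STING, fell by 0.99 and 0.86 on the log2 scale. Of the interferon ligands, IFNL1 fell with sgRNA 6 (-1.26 ± 0.51, 0.5 against 1.2 CPM), a call that was lost on leaving out any of 4 single libraries. No ligand was called with sgRNA 9, and the pair was not called as a list (adjusted p = 0.872 and 0.963; 0 higher and 1 lower, then 0 and 0, also adjusted over the list alone).

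**Figure D2:**
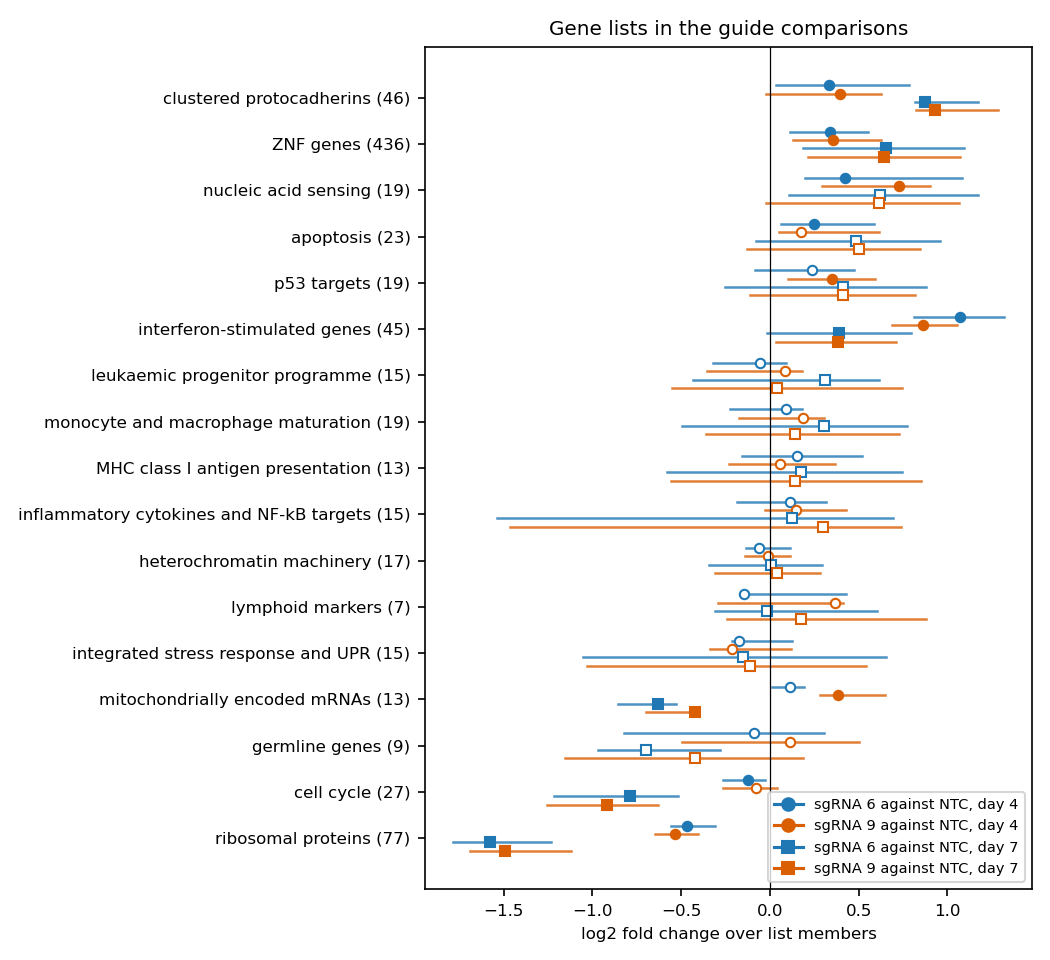
Median log2 fold change against NTC, with quartiles, of the members of each gene list with 7 or more tested members. Circles are day 4 and squares day 7, blue is sgRNA 6 and orange sgRNA 9, and filled symbols mark lists called by camera at the preset correlation. Ribosomal protein genes reach medians of -1.58 and -1.49 at day 7, and interferon-stimulated genes 1.07 and 0.86 at day 4.

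Other groups held genes that moved strongly in both directions at day 7, and none of these lists was called. Among MHC class I genes, NLRC5, the transactivator of the class, rose (1.46 ± 0.09 and 1.49 ± 0.09) while HLA-C (-0.90 ± 0.06 and -0.85 ± 0.06) fell, with 7 higher and 6 lower of 13 in each guide. Inflammatory genes had 6 of 15 higher and 5 lower with sgRNA 6, and 9 and 5 with sgRNA 9. CCL5 (-1.92 ± 0.08 and -1.81 ± 0.08) and TNF fell and the adhesion gene ICAM1 rose (2.14 ± 0.13 and 2.09 ± 0.14). The medians of this list were 0.13 and 0.30 but its means -0.35 and -0.25. Apoptosis genes had 15 of 23 higher and 5 lower with each guide, with MCL1 up (1.27 ± 0.09 and 1.19 ± 0.09) and BAX down (-1.36 ± 0.06 and -1.25 ± 0.06). Targets of p53 had 10 of 19 higher and 5 lower, then 11 and 3, with the ribonucleotide reductase subunit RRM2B up by 1.94 ± 0.14 and 1.79 ± 0.15. Monocyte and macrophage genes had 10 of 19 higher and 6 lower, then 9 and 7, with EGR1 down (-1.76 ± 0.12 and -1.54 ± 0.12). In the leukaemic progenitor programme 7 of 15 rose and 4 fell, then 7 and 3, with MYC down (-1.18 ± 0.05 and -1.15 ± 0.05) and HOXA11 up (0.96 ± 0.07 and 1.07 ± 0.07). The heterochromatin machinery had 6 of 17 higher and 6 lower, then 7 and 7, with ATF7IP up (1.36 ± 0.08 and 1.26 ± 0.08) and CBX5 down (-1.41 ± 0.07 and -1.40 ± 0.07). Stress response and UPR genes had 6 of 15 higher and 7 lower with each guide, with the serine synthesis enzyme PHGDH at -2.34 ± 0.08 and -2.41 ± 0.08 and ATF4 at -0.92 ± 0.05 and -0.77 ± 0.05. Germline genes had 1 of 9 higher and 4 lower, then 1 and 5, with the meiotic gene SYCP3 at -2.13 ± 0.20 and -2.09 ± 0.20. Of 7 lymphoid markers 1 rose and 2 fell, then 2 and 2, with PAX5 up (2.19 ± 0.22 and 2.09 ± 0.22) and NKG7 down (-2.16 ± 0.11 and -2.33 ± 0.11). With each guide 1 of 2 erythroid and megakaryocytic markers, GP9, fell, and 1 of 3 epithelial and fibroblast markers, COL1A1, rose. Adjusted over the list alone, these counts were the same except for monocyte and macrophage genes with sgRNA 6 (10 and 7). Camera direction, median and mean also differed in sign for lymphoid markers with both guides, for epithelial and fibroblast markers with sgRNA 6 and for the heterochromatin list with sgRNA 9. For all 20 lists and 4 comparisons, 26 of 80 tests were called at the preset correlation and 3 with an estimated one.

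Both guides changed largely the same genes. At day 4, 5338 genes were called in the same direction with both and 0 in opposite directions by edgeR (87.4% of the shorter list), against 1581 for independent lists of those sizes. At day 7 the numbers were 9387, 0 and 94.3%, against 3858. Pearson's r of the log2 fold changes across genes, which are not independent replicates, was 0.889 at day 4 and 0.982 at day 7. Both guides were set against the same NTC libraries, and unchanged groups simulated against them 10 times gave r of 0.530 and 0.569. The covariances were 0.174 and 0.857, against 0.0128 and 0.0147 simulated, differences of 0.161 and 0.842. With 3 NTC libraries per day the controls could not be split, so part of the excess may come from sharing them. Comparisons across guides and days share no library. Between sgRNA 6 at day 7 and sgRNA 9 at day 4, 6159 genes were called in the same direction and 109 in opposite ones (2597 for independent lists; r = 0.795), and between sgRNA 6 at day 4 and sgRNA 9 at day 7, 5482 and 125 (2329; r = 0.748). The same guide shared 5478 genes between days with sgRNA 6 (152 opposite) and 6099 with sgRNA 9 (111 opposite). In all 4 comparisons 2259 genes were higher and 2675 lower. With the mean of both guides against NTC, 7061 genes were called at day 4 (3368 higher, 3693 lower) and 10336 at day 7 (5400 higher, 4936 lower). With library totals in place of TMM these splits were 5402 and 2137, and 7567 and 3174.

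The guides differed at day 4 in interferon-stimulated genes, among other lists. ISG15, a ubiquitin-like antiviral protein, averaged 904 ± 59.9 CPM with sgRNA 9 and 1287 ± 47.2 CPM with sgRNA 6 (log2 difference -0.51 ± 0.06, adjusted p = 3.79e-05, n = 3 each), and ISG20 (-0.52 ± 0.08) and the metallothionein MT2A (-0.46 ± 0.07) were also lower with sgRNA 9. TBC1D30 (1.98 ± 0.33), SLC6A8 (1.33 ± 0.23) and SULF2 (1.68 ± 0.39) were higher, the last of them no longer called on leaving out any library of either guide but sgRNA 9 replicate 3. Of 45 interferon-stimulated genes 16 were lower and none higher with sgRNA 9 (28 and 0 adjusted over the list alone; median -0.21; camera adjusted p = 2.31e-31, and 0.0335 with an estimated correlation), and of 13 MHC class I genes 3 were lower (6 adjusted over the list alone; adjusted p = 8.97e-06, and 0.0431 with an estimated correlation). Camera also called mitochondrially encoded mRNAs (median 0.28; adjusted p = 1.58e-08, and 0.409 with an estimated correlation) and p53 targets (median 0.11; 0.00367, and 0.109) as higher, and nucleic acid sensing (median -0.10; 3 of 19 lower, 7 lower and 1 higher adjusted over the list alone; 0.00786, and 0.182) and ribosomal protein genes (median -0.07; 3.70e-07, and 0.617) as lower with sgRNA 9. In edgeR 0 of 13 mitochondrial, 0 of 19 p53 and 0 of 77 ribosomal genes were called (10, 0 and 0 adjusted over the list alone; 10, 7 and 8 at an unadjusted p under 0.05), and DESeq2 also called 0, with no adjusted p for 0, 13 and 19 of them. These list tests were added later. Altogether 94 genes were called (45 higher, 49 lower), out of 1767 with an unadjusted p under 0.05. That count depended on single libraries. It was 26 and 23 without sgRNA 6 replicate 2 and 3, 21 without sgRNA 9 replicate 1 or 2 and 292 without sgRNA 9 replicate 3. A fit of only these groups called 29, and DESeq2 152. At day 7 there were 12 (2 higher, 10 lower; 1915 at an unadjusted p under 0.05). The lipogenic regulator SREBF1 (0.38 ± 0.06) and RGMA (0.73 ± 0.15) were higher with sgRNA 9, and the proteoglycan VCAN (-0.56 ± 0.10), HIPK2 (-0.69 ± 0.14) and KIAA0754 (-0.78 ± 0.15) lower. The number of calls at day 7 fell to 0 in edgeR on leaving out sgRNA 6 replicate 1, sgRNA 9 replicate 1 or sgRNA 9 replicate 2, and to 4 and 5 without sgRNA 6 replicate 2 and sgRNA 9 replicate 3. DESeq2 called 73 with all libraries, and a fit of only these groups 385. Among the lists, camera called ribosomal protein genes (median 0.08; adjusted p = 2.56e-08), mitochondrially encoded mRNAs (0.17; 8.50e-06) and inflammatory genes (0.11; 0.0482) as higher and cell cycle genes (-0.07; 0.000443) as lower with sgRNA 9 at day 7, and none of these with an estimated correlation (0.594, 0.553, 0.696 and 0.617). In edgeR 0 of their 77, 13, 15 and 27 members were called (0, 4, 2 and 4 adjusted over the list alone; 12, 5, 3 and 6 at an unadjusted p under 0.05), and in DESeq2 only 1 cell cycle gene, with no adjusted p for 14 ribosomal and 8 inflammatory genes.

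The NTC cells also changed between the days, and these libraries set the baseline of each day. IFI27, an interferon-stimulated gene, rose from 95.3 ± 3.44 to 1404 ± 139 CPM (log2 fold change 3.88 ± 0.08, adjusted p = 8.6e-25, n = 3 each), and the chemokine genes CCL4L2 (4.48 ± 0.38) and CCL3L3 (2.79 ± 0.20), which have near-identical copies, rose too. FOSB (-1.54 ± 0.38), ZKSCAN8 (-1.53 ± 0.44) and the stem cell factor receptor KIT (-1.52 ± 0.22) fell. Of 13004 genes, 3726 were called (1727 higher, 1999 lower), and 302 changed 2-fold or more (259 higher, 43 lower).

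The change against NTC differed between the days for many genes. TDO2 rose more at day 7 by 3.91 ± 0.31 with sgRNA 6 and 3.68 ± 0.30 with sgRNA 9, and the matrix protease MMP9 by 3.64 ± 0.71 and 3.24 ± 0.65. TNF moved the other way (-3.26 ± 0.27 and -3.03 ± 0.26), as did CCL4L2 (-3.49 ± 0.89 and -3.26 ± 0.84). The difference for CCL4L2 was smaller than its rise in NTC between the days. FPR3 was also called (4.21 ± 1.35 and 4.33 ± 1.37), but not without NTC day 4 replicate 3 (adjusted p = 0.188 and 0.189). HIST1H2BH with sgRNA 6 (-2.65 ± 0.26) and TBC1D30 with sgRNA 9 (-2.52 ± 0.53) completed the largest shifts. With sgRNA 6, 7191 genes were called (3555 higher, 3636 lower), and with sgRNA 9, 6298 (3046 higher, 3252 lower). Library totals in place of TMM gave 5059 and 2406, and 4769 and 2032.

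**Figure D3:**
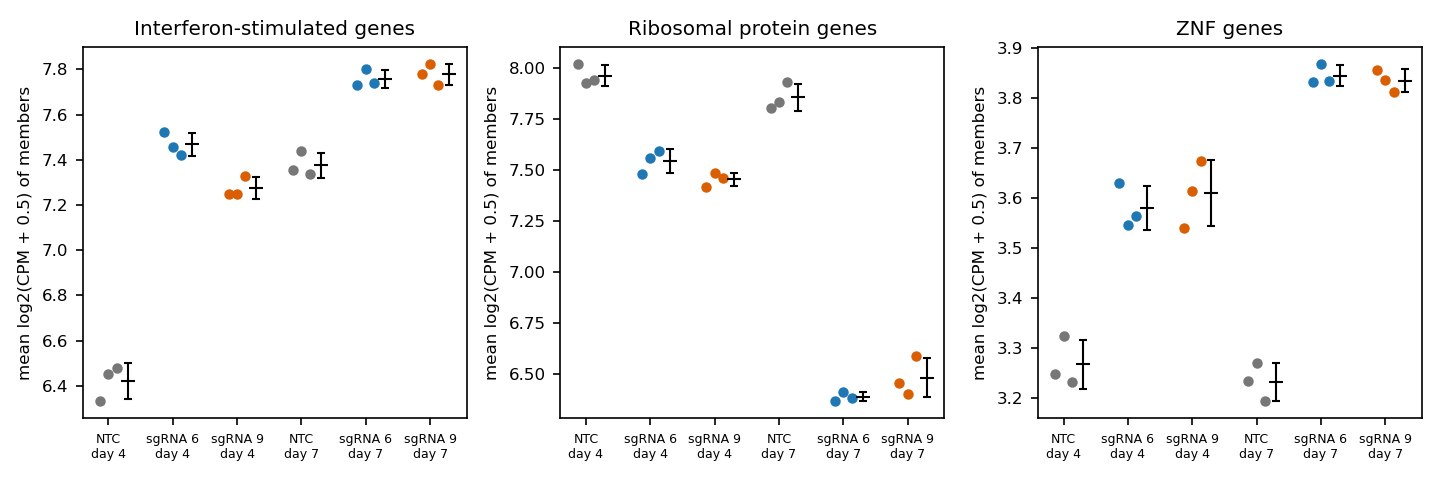
Mean log2(CPM + 0.5) of the members of 3 gene lists in each library, by group and day. The vertical axes do not start at 0. Interferon-stimulated genes rise in NTC between the days, and ribosomal protein genes are lowest in the guide libraries of day 7.

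Among the repeats called, the satellite SST1 rose most in each comparison, followed by the endogenous retrovirus HERV3 except with sgRNA 9 at day 4. There the satellite SATR2 rose by 1.29 ± 0.35 (adjusted p = 0.0274), a call lost without sgRNA 9 replicate 1 (0.0807) or 3 (0.05001) or NTC replicate 1 (0.210) or 2 (0.0542). SST1 reads per M gene counts averaged 108 ± 15.0 with sgRNA 6 and 117 ± 21.6 with sgRNA 9 at day 4, against 16.04 ± 1.254 in NTC (log2 fold changes 2.75 ± 0.14 and 2.87 ± 0.14, n = 3 each). At day 7 they averaged 250 ± 21.0 (n = 3) and 226 ± 17.6 (n = 2) against 18.9 ± 0.984 (3.72 ± 0.14 and 3.58 ± 0.15). HERV3-int, whose envelope gene is ERV3-1, so that both tables may count the same reads, rose by 1.26 ± 0.16 and 1.22 ± 0.16 at day 4 and 2.95 ± 0.16 and 2.83 ± 0.17 at day 7, and its long terminal repeat LTR4 rose in all 4 comparisons, with 1.12 ± 0.20 for sgRNA 9 at day 4 and 2.46 ± 0.19 and 2.31 ± 0.20 at day 7. Other internal parts of retroviruses among the largest rises were HERVP71A-int (1.22 and 1.16) and THE1C-int (1.02 and 0.88) at day 4, and LTR23-int (2.23 and 2.12) and MSTC-int (1.59 and 1.53) at day 7. The DNA transposon Ricksha_a fell in all 4 comparisons (-0.97 ± 0.12, -1.17 ± 0.12, -2.62 ± 0.14 and -2.69 ± 0.16), MER103C by -0.86 with each guide at day 4, and LTR06 (-1.79 and -1.68) and MamGypLTR1b (-1.57 and -1.55) at day 7.

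Of 1012 subfamilies, edgeR called 56 with sgRNA 6 at day 4 (28 higher, 28 lower), 56 with sgRNA 9 (24 and 32), 302 with sgRNA 6 at day 7 (146 and 156) and 230 with sgRNA 9 (124 and 106). Single libraries moved these counts. With sgRNA 6 at day 4 the count was 24 without NTC replicate 1 and 31 without NTC replicate 3. With sgRNA 9 it was 22 and 34 without NTC replicate 1 and 2, and 36 and 33 without sgRNA 9 replicate 1 and 2. At day 7 it was 138 without sgRNA 9 replicate 1 and also without replicate 3. With the plain gene total in place of TMM the splits were 73 and 10, 51 and 11, 497 and 65, and 473 and 49. Without the 2 day 4 libraries rich in repeat reads, the day 4 splits leaned to falls. They were 28 higher and 79 lower with sgRNA 6, and 28 and 126 with sgRNA 9. No subfamily differed between the guides in edgeR (11 at day 4 and 12 at day 7 had an unadjusted p under 0.05). LTR elements made up 542 of the subfamilies and 21 of the 28 that rose with sgRNA 6 at day 4 (Fisher's exact test, adjusted p = 0.0495), 15 of 24 with sgRNA 9 (0.443), 96 of 146 with sgRNA 6 at day 7 (0.00870) and 82 of 124 with sgRNA 9 (0.00908). Among the falls they numbered 11 of 28 and 15 of 32 at day 4 (Fisher's exact test, adjusted p = 0.259 and 0.585). At day 7 they were 76 of 156 and 51 of 106 falls (0.337 and 0.375). The test treats subfamilies as independent, although they can share reads. SINE subfamilies had 0 among the rises in edgeR (Fisher's exact test, adjusted p = 0.443 and 0.625 at day 4, 0.00486 and 0.00908 at day 7). Alu subfamilies had 11 and 6 of 41 lower at day 7, but SINE falls were not enriched then (Fisher's exact test, adjusted p = 0.129 and 0.455). DNA transposons made up 208 of the subfamilies but 14 of 146 and 14 of 124 rises at day 7 (Fisher's exact test, adjusted p = 0.00366 and 0.0162, and 0.350 with each guide at day 4). Of 43 family totals, limma called 6 (3 higher, 3 lower), 5 (2 and 3), 15 (3 and 12) and 9 (3 and 6). As a share of the repeat table total the counts were mostly higher, with 5 higher and 3 lower, 6 and 2, 21 and 5, and 14 and 4. That total includes ribosomal RNA, which made up 40.3 ± 2.73% of it in NTC and 32.7 ± 2.86% with sgRNA 6 at day 7 (SD). At day 4 the ribosomal RNA shares were 33.0% in NTC, 32.7% with sgRNA 6 and 32.1% with sgRNA 9. How far this moved the counts of family totals was not tested. With sgRNA 9, 8 were called at day 4 without its replicate 1, and 5 and 4 at day 7 without its replicate 1 and 3. The centromeric satellite family, which holds SST1, rose by 1.68, 1.72, 2.53 and 2.37. Totals of ERV1, ERVK, ERVL, L1 and Alu were not called in any of the 4 comparisons, with ERV1 at 4718 ± 524 and 4638 ± 493 reads per M gene counts at day 4 against 4637 ± 227 in NTC.

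**Figure D4:**
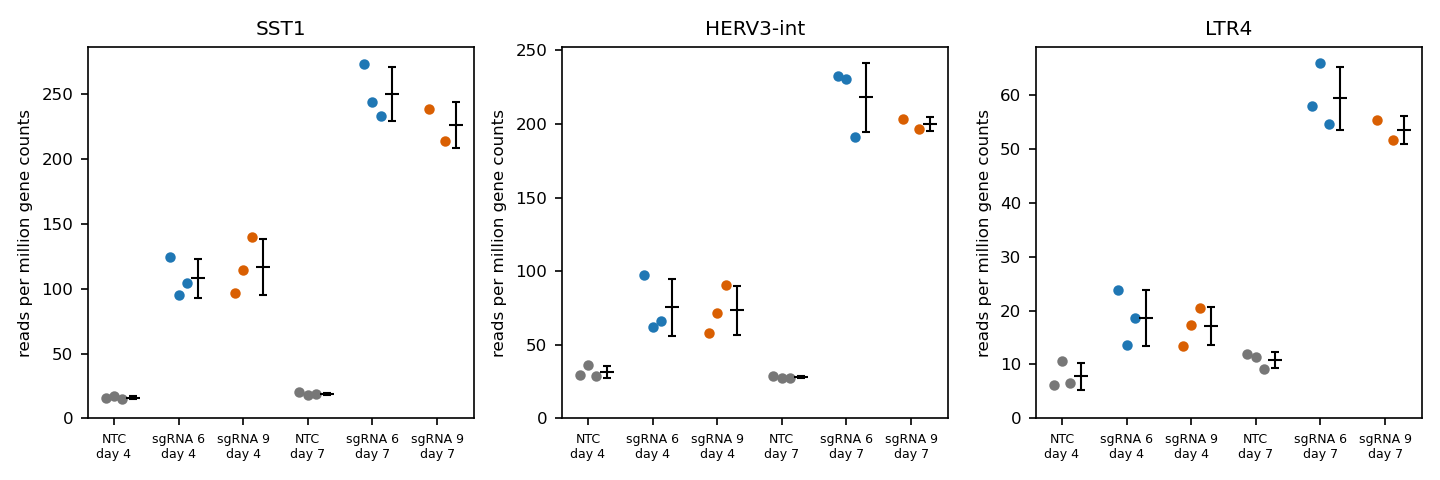
Reads of SST1, HERV3-int and LTR4 per M gene counts in each library, by group and day. Points are libraries and bars show mean with SD, with n = 3 per group except sgRNA 9 at day 7 (n = 2). SST1 lies at 108 and 117 in the guide groups of day 4 and 250 and 226 in those of day 7, against 16.04 and 18.9 in NTC.

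The authors' deposited tables list 2493 genes for sgRNA 6 and 3052 for sgRNA 9 at day 4, and 7733 and 7525 at day 7, with SETDB1 at -0.79, -0.82, -0.67 and -0.59 in log2 fold change. The largest FDR in these lists was 9.99e-05, a stricter cutoff than the one used here. Their lengths therefore cannot be compared with the numbers of calls above. Of the listed genes tested here (2493, 3052, 7720 and 7511), every one was called in the same direction. Pearson's r across these genes was 1.00 in each comparison. The lists come from the same libraries, and the submitters' notes also name edgeR. The match is therefore no independent check of the calls.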

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

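The tests of TMM scaling for ribosomal protein and ZNF genes, of a shift shared by all genes, of the rise in NTC cells, of a collection batch, of unspliced RNA or DNA and of the gene count denominator, and all list tests of the difference between days, were chosen only after the result was seen.

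The change against NTC differed between day 4 and day 7 by edgeR's test of that difference for 7191 genes with sgRNA 6 and 6298 with sgRNA 9, and for 59 and 18 repeat subfamilies. Camera tests of the same difference called 6 lists with each guide at the preset correlation. The median day 7 minus day 4 change on the log2 scale, sgRNA 6 before sgRNA 9, was -1.09 and -0.96 for ribosomal protein genes, -0.82 and -0.81 for mitochondrially encoded mRNAs, -0.68 and -0.77 for cell cycle genes, -0.61 and -0.47 for interferon-stimulated genes, 0.29 and 0.25 for ZNF genes and 0.44 and 0.70 for clustered protocadherins. Library totals gave 0.50 and 0.45 for ZNF genes, or 0.27 and 0.23 relative to all genes, and -0.40 and -0.27 for interferon-stimulated genes, or -0.62 and -0.49. With an estimated correlation none of these list calls held, with adjusted p of 0.109 and 0.109, 0.617 and 0.520, 0.208 and 0.109, 0.154 and 0.221, 0.513 and 0.423, and 0.513 and 0.276. The guides themselves differed in 94 genes at day 4 and 12 at day 7. In the sgRNA 9 day 7 replicate 2 library, which the repeat comparison left out, SST1 lay at 160 reads per M gene counts, above the 18.0 to 19.98 of the NTC libraries of that day. Other repeats in it lay far below NTC, with HERV3-int at 1.28 and LTR4 at 0.903 (lowest NTC library 27.67 and 9.09). Its transposable element reads were 9016 per M gene counts, against 81268 and 89862 in replicates 1 and 3. Its SST1 level therefore cannot be read as a further replicate.

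Splits of the same libraries into other groups of the same sizes were counted. For the mean of both guides against NTC, 1 of 84 splits (the real one) gave as many calls at day 4 (6537, highest other 0) and 1 of 84 at day 7 (10204, highest other 0). This is a share under 0.05, so random groupings of these libraries rarely give as many. It does not exclude a chance difference between cultures, if the libraries of a group are not separate cultures. For a single guide, 10 splits are too few for a share under 0.05. In these fits of 6 libraries the real split called 5647, 6239, 10015 and 9882 genes (sgRNA 6 and sgRNA 9 at day 4, then at day 7) with a highest other of 0, the guides differed in 29 genes at day 4 (highest other 0) and 385 at day 7 (highest other 1), NTC days differed in 3463 (highest other 0), and repeats gave 41, 49 and 432 (highest other 2, 6 and 0, without sgRNA 9 at day 7, which has 2 libraries), with 1 of 10 splits as large each time. Gene lists gave as many calls or more in 5, 4, 4 and 6 of 10 splits, the real one included (real 6, 7, 6 and 6, highest other 7, 9, 8 and 7). The number of lists called at the preset correlation was therefore matched or exceeded by groups that mix guide and NTC libraries in each comparison. Those mixed groups still hold guide libraries unevenly, so part of the guide change can remain in them. They are no baseline without change, and the number of lists called cannot decide about chance here. For the difference between days, 8 of 100 splits gave as many genes with sgRNA 6 (7089, highest other 8588) and 8 of 100 with sgRNA 9 (6228, highest other 8160), and this count decides nothing about chance. The 7 others as large all keep the day 7 guide and NTC libraries apart and regroup those of day 4, which turns the change at day 7 into a difference between days. Splits that mix the day 7 libraries called at most 21 and 0.

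Ribosomal protein genes fell and ZNF genes rose at day 7 with both guides. The tables argue against GC content and transcript length as the whole cause, since the members still differed from 20 tested genes nearest in both by a median of -1.08 (ribosomal) and 0.53 (ZNF) in the guide closest to 0. For ribosomal protein genes TMM scaling is argued against too, since library totals alone gave a median of -1.13, or -1.55 relative to all genes. For ZNF genes the median of 1.00 with library totals decides nothing, because totals also put the median of all genes above 0, at 0.42. A shift shared by all genes is argued against as the whole cause, since ZNF genes lay 0.58 above the median of all genes with library totals. Reads shared with ribosomal protein pseudogenes or between ZNF genes were not tested and stay open, as does a change that follows slower growth, which the fall of cell cycle genes would be consistent with. A response to SETDB1 loss is the explanation the design names, and it was not separated from these.

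Interferon-stimulated genes were raised less against NTC at day 7 than at day 4. TMM scaling is argued against as the cause, since library totals alone still gave a median difference of -0.27 in the guide closest to 0, or -0.49 relative to all genes. A rise in the NTC cells is a candidate explanation whose values are there. NTC rose by a median of 0.87 between the days and the guide groups by less, 0.26 in the lower of them, so the level in guide cells did not fall. Whether NTC rose through time in culture or a collection batch cannot be told apart, because day and collection coincide and 9 lists outside interferon and sensing were also called in NTC between the days.

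In 2 day 4 guide libraries, sgRNA 6 replicate 1 and sgRNA 9 replicate 3, 680 and 685 of 709 subfamilies were higher than in the other 2 libraries of their group. Fewer gene counts as the denominator are argued against, since gene counts were 96.5% and 96.4% of the others, too small a gap for 25.2% and 23.9% more repeat reads. More reads from unspliced RNA or DNA could be the source, since the share of gene counts in genes below the filter exceeded the next library by 17.8% and 5.33%, against gaps of 2.12% and 2.72% between the other libraries. The rule for reading that test was changed after its value was seen, and 2 libraries without intron counts do not decide it, so it stays open. No biological explanation was tested, since the libraries share their labels with the rest of their groups.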

How the results depend on the processing

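Among the alternatives, library totals without TMM and the fit without the 2 day 4 libraries rich in repeat reads were chosen after the data were seen, and the others before the data were examined. Depth of 10.58 M to 13.96 M gene counts limits genes with few counts, such as FPR3 and IFNB1, and the repeat table gives no position of a repeat. SETDB1 stayed lower and called under RLE size factors, library totals, DESeq2, no filter, both blocks, fits of only the groups compared, the fit without the 2 libraries rich in repeat reads (day 4) and each library left out, from -0.86 to -0.65 (sgRNA 6) and -0.88 to -0.67 (sgRNA 9) at day 4 and from -0.72 to -0.29 and -0.60 to -0.21 at day 7, where the value closest to 0 came from library totals without TMM. A log2 fold change of 1 or more was required only in counts of genes, and SETDB1 does not reach it. For alternatives below that give another value, the cause was not tested unless stated.

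Gene calls. RLE size factors moved no count of called genes by more than 1.5 times and no call of a named gene. Without a filter on low counts the guides differed in 191 genes at day 4 and 148 at day 7, and DESeq2 called 152 and 73. Fits of only the groups compared gave 29 and 385 for the guide difference. Library totals without TMM gave 62 at day 4, and the fit without the 2 day 4 libraries rich in repeat reads 323. At a log2 fold change of 1 or more, which by construction keeps fewer genes, the counts were 320, 335, 3733 and 3404 for the 4 guide comparisons, 299 and 3583 for the mean of both guides, 8 and 0 in edgeR for the guide difference (94 and 12 without the minimum, 1767 and 1915 at an unadjusted p under 0.05), 1567 and 1001 for the day differences and 302 for NTC between days. The genes shared were then 187 and 3154 between guides at day 4 and day 7, 235 and 269 between days for sgRNA 6 and sgRNA 9, 275 for sgRNA 6 at day 7 with sgRNA 9 at day 4, and 231 for the reverse. At adjusted p 0.01 the overlaps moved by less than 1.5 times. Leaving out 1 library gave 5114 to 5882 genes for sgRNA 6 and 5777 to 6412 for sgRNA 9 at day 4, 9704 to 9823 and 9556 to 9684 at day 7, 6012 to 6996 and 9928 to 10294 for the mean of both guides, 6738 to 7216 and 5781 to 6226 for the day differences, and 2837 to 3479 for NTC. The guide difference ranged from 21 (without sgRNA 9 replicate 1 or 2) to 292 (without sgRNA 9 replicate 3) at day 4, with 26 and 23 without sgRNA 6 replicate 2 and 3, and from 0 to 12 at day 7, with 4 without sgRNA 6 replicate 2 and 5 without sgRNA 9 replicate 3. SETDB1 ranged from -0.86 to -0.74, -0.88 to -0.76, -0.72 to -0.62 and -0.59 to -0.54.

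Named genes. Of 351 results, library totals without TMM ended 9 calls and turned GNLY with sgRNA 6 at day 7 to 0.0220 (adjusted p = 0.863). The median of all genes in that comparison lay at 0.42 with totals and 0.05 with TMM. DESeq2 ended 2 of 346 (MT-CO1 with sgRNA 6 at day 4, adjusted p = 0.151, and CD7 with sgRNA 9 at day 7, 0.117), and gave no adjusted p for TBC1D30 and SULF2 (guide difference, day 4) and RGMA, KIAA0754 and HIPK2 (day 7). Without a filter 1 call ended, without the 2 libraries rich in repeat reads 2 of 175, and leaving out 1 library 52 of 2178, spread over 19 results.

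Replicate numbers. Libraries of a day with the same number did not deviate together (median r = 0.02, highest 0.0889, none of 18 pairs over 0.1), so no pairing by number was seen. Of the pairs of a day with unlike numbers, 5 of 36 were over 0.1. Across days it was 4 of 27 with the same number and 3 of 54 with unlike numbers. Weak pairing is not excluded. With the number as a replicate block 36 repeats were called with sgRNA 6 at day 4. As a block within day, the guide difference at day 7 fell to 0 calls in edgeR and NTC between days gave 2320, and 5 named genes of the guide difference lost their call. The block changed no other count by over 1.5 times and no call of a gene list or named repeat.

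Gene lists. With an estimated correlation 2, 1, 0 and 0 lists were called in the 4 guide comparisons in place of 7, 7, 6 and 6, and 23 of 80 tests lost their call, interferon-stimulated genes at day 7 among them (adjusted p = 0.720 and 0.696, against 0.00976 and 0.00229). Library totals without TMM ended the calls of apoptosis (0.0992) and cell cycle (0.360) genes with sgRNA 6 at day 4 and of mitochondrially encoded mRNAs with sgRNA 9 at day 7 (0.0866). Without the 2 libraries rich in repeat reads, apoptosis and cell cycle genes with sgRNA 6 at day 4 were not called (0.0578 each) and mitochondrially encoded mRNAs were (0.0382). Without NTC day 7 replicate 2 nucleic acid sensing was called with each guide at day 7 (0.0455). Leaving out 1 library gave 6 to 8 lists with sgRNA 6 at day 4 and 6 to 7 in each other comparison, and interferon-stimulated genes had adjusted p of 6.24e-46 to 1.57e-38 and 2.25e-29 to 7.73e-27 at day 4, and 0.00500 to 0.0218 and 0.000833 to 0.00403 at day 7.

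Repeats. With the repeat table's own total and TMM, 210, 213, 520 and 435 subfamilies were called. With the plain gene total the counts at day 7 were 562 and 522, and with DESeq2 161, 169 and 384 (both guides at day 4, sgRNA 9 at day 7). With sgRNA 9 day 7 replicate 2 kept, 1 was called in each comparison (SST1 each time), and 36 of 40 named results lost their call. Without the 2 day 4 libraries rich in repeat reads 107, 154 and 353 were called (both guides at day 4, sgRNA 9 at day 7). At day 4 these were 28 higher and 79 lower with sgRNA 6, and 28 higher and 126 lower with sgRNA 9. The median log2 fold change of all subfamilies was then -0.12 with each guide, against 0.02 and 0.006 in the main fit. Leaving out 1 library gave 24 to 60 and 22 to 63 at day 4, and 225 to 263 and 138 to 183 at day 7, where 138 came without sgRNA 9 replicate 1 and without replicate 3, each leaving a lone library assumed to vary like the other groups. Named results lost 12 of 230 calls this way, all of LTR60, SATR2 and Eulor9A. DESeq2 gave no adjusted p for SATR2 and Eulor9A. As a share of the repeat table total, 8, 26 and 18 families were called (sgRNA 9 at day 4, both guides at day 7), and DNA/hAT-Charlie and Other/Other with sgRNA 6 at day 7 turned to 0.0150 and 0.0213. Without the 2 libraries rich in repeat reads 10 and 15 were called with sgRNA 9 (day 4, day 7). Leaving out 1 library gave 5 to 8 and 4 to 8 families at day 4, and 11 to 16 and 4 to 9 at day 7.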

Other observations

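The test of histone genes as a class, and the list tests in NTC cells, were chosen only after the result was seen.

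In NTC cells, interferon and inflammatory genes rose between day 4 and day 7. Of 45 interferon-stimulated genes 41 rose and none fell (42 and 0 adjusted over the list alone; median log2 fold change 0.87; camera adjusted p = 2.77e-57, and 0.00727 with an estimated correlation). Inflammatory cytokines and NF-kB targets had 13 of 15 higher and none lower (median 1.29; adjusted p = 3.80e-15, and 0.0431 with an estimated correlation), and both interferon ligands tested rose (adjusted p = 0.0413, and 0.208 with an estimated correlation). MHC class I genes (9 of 13 higher, 1 lower), nucleic acid sensing genes (11 of 19 higher, 2 lower), monocyte and macrophage genes (13 of 19 higher, 2 lower) and stress response genes (10 of 15 higher, none lower) were called upward, with adjusted p of 0.0301, 0.0431, 0.0431 and 0.0431 with an estimated correlation. Cell cycle genes fell (25 of 27, median -0.29; adjusted p = 5.48e-14, and 0.159 with an estimated correlation), and 5 of 17 heterochromatin genes and 20 of 46 protocadherins were lower (adjusted p = 0.0217 and 0.00364, and 0.183 and 0.660 with an estimated correlation). Ribosomal protein genes had 28 of 77 lower and 2 higher (median -0.13; 0.741 with an estimated correlation), and mitochondrially encoded mRNAs 4 of 13 higher (0.807 with an estimated correlation).

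A larger rise of ZNF genes on chromosome 19, where many of them lie in clusters that SETDB1 is known to cover, was tested as a hypothesis. At day 7 the mean log2 fold change of 214 ZNF genes on chromosome 19 exceeded that of 221 elsewhere by 0.0778 with sgRNA 6 and 0.0883 with sgRNA 9 (permutation p = 0.273 and 0.182), so the hypothesis failed for that day. At day 4 the difference was 0.13 with each guide (permutation p = 0.00013 and 0.00052, adjusted p = 0.000520 and 0.00104). The permutation treats ZNF genes as independent, although many lie in clusters, and both guides share the NTC libraries. Its p-values therefore do not measure the spread between libraries and can be too small. Other genes on chromosome 19 (804) averaged -0.08 and -0.12 at day 4.

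HIST1H2BH was among the largest falls at day 7, and a fall of the replication-dependent histone genes as a class was tested. It was not found among the 13 that passed the filter. The test cannot decide about the class, since histone genes below the filter are not covered. How well the library kit captures histone transcripts was not examined either. Of 13 histone cluster genes tested, 2 fell 2-fold or more with each guide (15.4%, against 11.99% and 11.03% of other genes), and 10 rose.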
